A study of Mus musculus with 12 samples.

How the data were processed

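The samples were 12 pools of jejunal epithelium RNA from male mice, 3 pools of 3 mice in each of 4 groups formed by genotype (wild-type or POR-null) and diet (control or quercetin). Each pool was hybridised to 1 one-colour Affymetrix 430A array, and mice were housed 3 per cage per the labels. The deposited values are log2 intensities per probe set, processed by the authors. The submitters' processing notes name MAS5 and RMA without a role or version, so which of them made the values is not given in the sources used here. Array medians were 5.94 to 6.01, the lowest values 2.69 to 2.81 and the highest 13.96 to 14.14, so the arrays were taken to share a scale and were not normalised again.

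Of 22690 probe sets, 64 control probe sets were left out and 22626 were tested. The platform table gave 1 gene symbol to 20380 probe sets, several to 691 and none to 1555. Of the single-symbol probe sets, 20351 had an Entrez ID in the mouse RefSeq table, and 0 symbols were updated through it. Each of 12393 genes was represented by its single-symbol probe set with the highest mean, leaving out cross-hybridising types where the gene had another. The targeted gene was not analysed here.

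A linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (8 residual and 6.75 prior degrees of freedom). The 7 contrasts were the quercetin effect in each genotype, the genotype effect on each diet, their interaction, and the average quercetin and genotype effects. Moderated p, two-sided, were adjusted by Benjamini-Hochberg over all tested probe sets within a contrast, and a probe set was called at an adjusted p under 0.05. Values of single genes and probe sets are log2 differences ± SE of the model. Means of gene lists are given ± the SD over their genes, which is not the precision of the effect between pools. Levels in a group are means ± SD over its pools. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

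The design, the alternatives, the naming rule and 37 gene lists (24 of pathways and intestinal segments and 13 of cell type markers) were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 37 lists within a contrast. They were tested again with a correlation estimated from the data, with the directional test of fry, and, for the average effects, by two-sided exact permutation of the list means within strata (400 relabellings, smallest p 0.005). The permutation was added after seeing the data. For 3 pools against 3, the two-sided exact p of a list mean cannot go under 0.1. List calls in data with no effect were counted in 100 sets of rotated residuals for each contrast.

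Named genes were those past the test, filled up with the smallest p to 5 in each direction, and up to 4 members with the smallest p of each list that was called or had a member past the test. Cyp1a1, Cyp3a11, Nqo1 and Fabp6 were always looked up (4 measured of 6 fixed). Unnamed gene models were passed over. The segment score of a pool is its mean of distal markers minus its mean of proximal markers, each gene centred over the 12 arrays.

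The pipeline was tested on simulated data in which 50 probe sets each were changed by log2 values of 0.5, 1, 2 and 3. At 0.5, the share recovered was 44% to 64% for the contrasts of 3 pools against 3 and 86% to 88% for the averages, and at 1 it was 94% to 100%. No recovered probe set had the wrong sign, and 8 to 19 unchanged probe sets were called per contrast. The noise was independent between probe sets. All changes were present at once, which makes the adjusted threshold easier to reach than in contrasts with few calls. The shares are therefore not the chance of detection in the real contrasts. In the average genotype effect Fdft1 (1.40) was not called.

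The alternatives tried were quantile normalization, median centring, a filter on dim probe sets, a fit of only the arrays compared, a trend and robust variance model, array weights, a block for the replicate number, 1 probe set or the mean of all probe sets per gene, and leaving out each array in turn. Leaving out the 3 arrays highest in smooth muscle markers and a fit with the segment score as a covariate were added after seeing the data.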

Results

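Transcript levels were measured in the jejunum, the middle of 3 equal parts of the small intestine, of male mice of the C57BL/6 strain aged 6 to 8 weeks. NADPH-cytochrome P450 reductase (POR) is the enzyme that hands electrons to the microsomal cytochromes P450 and to several enzymes of sterol synthesis. Mice were labelled wild-type or POR-null, with the tissues of deletion not stated. They ate a soya-free control diet or the same diet with quercetin, a plant flavonol, at 6.2 g per kg of diet (7 mg per mouse) for 24 hours after 14 days of adaptation. The 4 groups were wild-type mice on the control diet, wild-type mice on quercetin, POR-null mice on the control diet and POR-null mice on quercetin, with 3 arrays each. Each of the 12 arrays carried RNA of scraped epithelium pooled from 3 mice, so n = 3 pools in every group and differences between single mice are not seen. The number of arrays limits the precision of every value below.

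The 12 arrays resembled each other closely. Correlations across probe sets were 0.991 to 0.995 within groups and 0.989 to 0.995 between groups, and no 2 arrays held identical values (at most 2.84% of probe sets were equal to 2 decimals). The median SD between pools of a group was 0.12 log2 units. The targeted gene was not analysed here, so the genotype labels were not checked on it, and the labels do not state in which tissues it is deleted. Smooth muscle markers, from the muscle layers under the epithelium, varied more within groups than between them. Their mean log2 level, centred over all arrays, was 0.76 in wild-type control pool 3, 0.52 in POR-null control pool 1 and 0.21 in POR-null quercetin pool 1, against -0.30 to 0.07 in the other 9 pools.

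The first question was how the jejunum of POR-null mice differed from that of wild-type mice over both diets. Genes of cholesterol synthesis stood out. The list of 19 measured sterol genes was higher in POR-null mice by a mean of 0.72 ± 0.44 log2 units (SD over genes), which is 1.65-fold, and 18 of the 19 lay above 0. Hmgcs1, which makes the HMG-CoA used by the pathway, was 2.43-fold higher (log2 1.28 ± 0.23, SE, n = 6 pools per genotype). Squalene synthase Fdft1 was 2.64-fold higher (1.40 ± 0.26), lanosterol synthase Lss 1.39-fold (0.48 ± 0.09), the reductase Hsd17b7 1.41-fold (0.50 ± 0.08) and the lanosterol demethylase Cyp51, itself a P450, 2.65-fold (1.41 ± 0.38). Srebf2, the transcription factor that drives the pathway, was 1.28-fold higher (0.36 ± 0.07). Cyp51 and Srebf2 were picked out here after their values were seen.

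Adjusted over the list alone, 17 of the 19 sterol genes rose, while none passed when adjusted over all 22626 probe sets. The 2 that did not pass were Ebp (0.14 ± 0.08) and Sc5d (-0.02 ± 0.16). As a group the list rose by camera (adjusted p = 1.5e-37), though not with the correlation between its genes taken from the data (adjusted p = 0.161 with an estimated correlation). An exact permutation of the list means within each diet gave p = 0.015, or 0.185 after Benjamini-Hochberg adjustment over 37 lists. By limma 0 probe sets passed for this comparison, with 1133 at an unadjusted p under 0.05 against 1131 by chance. Without a single pool other than POR-null control pool 3 the count was 0 to 3. At the looser adjusted p of 0.1, 30 probe sets passed, 24 of them higher in POR-null mice, and 11 of the 30 belonged to 7 genes of the sterol list.

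The per-pool values of the sterol list set 1 pool apart. The mean was -0.43 ± 0.26 (SD) in wild-type control pools, -0.29 ± 0.10 in wild-type quercetin pools and 0.49 ± 0.05 in POR-null quercetin pools. POR-null control pools 1 and 2 lay at 0.63 and 0.53, whereas pool 3 lay at -0.47, within the wild-type range of -0.67 to -0.15. Without that pool the average genotype difference of the list was 0.89 (1.86-fold), 15 of its 19 genes passed over all probe sets, and the adjusted p was 0.00521 with an estimated correlation. The count over all genes was then 47 probe sets, 42 of them higher, of which 23 were of sterol genes. The pool was singled out by its low sterol values, so these values without it are not independent evidence for the sterol genes.

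**Figure D1:**
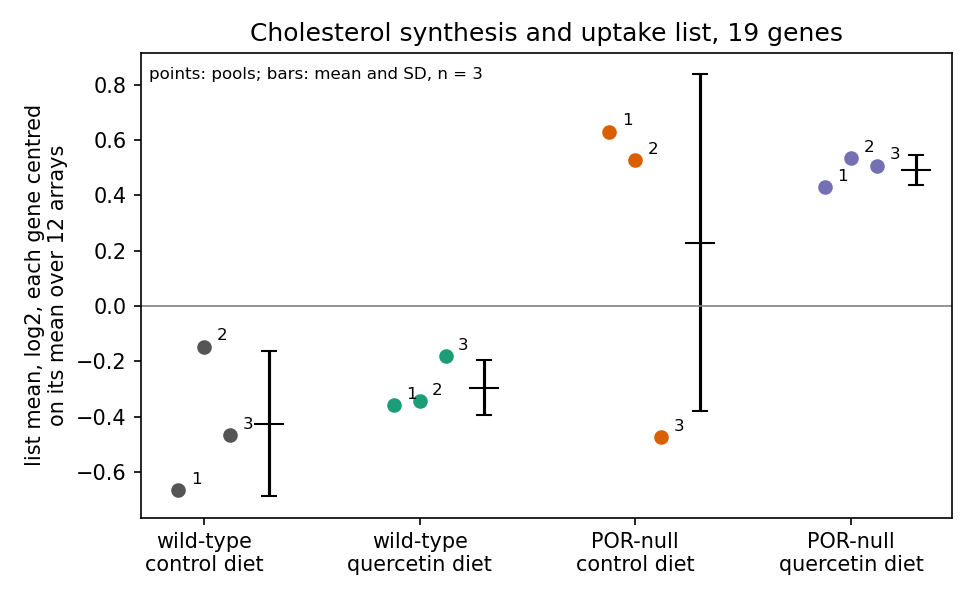
Mean log2 level of the 19 cholesterol synthesis and uptake genes in each pool, each gene centred on its mean over the 12 arrays; points are pools with their replicate number, bars the group mean and SD (n = 3). The POR-null pools lie between 0.43 and 0.63 except control pool 3 at -0.47, and the wild-type pools lie between -0.67 and -0.15.

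Other lipid genes differed with genotype as well. The fatty acid synthesis list was higher in POR-null mice by 0.17 ± 0.36 over 17 genes (camera adjusted p = 0.00069; adjusted p = 0.242 with an estimated correlation; permutation p = 0.025, or 0.231 adjusted over 37 lists). Adjusted over the list alone 4 members rose and 1 fell, against 0 over all genes. The stearoyl-CoA desaturase Scd2 was 2.70-fold higher (1.44 ± 0.26), the acetyl-CoA synthetase Acss2 higher by 0.34 ± 0.07 and fatty acid synthase Fasn by 0.33 ± 0.10, while Mlxipl, a carbohydrate-responsive transcription factor, differed by -0.22 ± 0.07. Fatty acid oxidation genes were lower, by a mean of -0.14 ± 0.18 over 28 genes (camera adjusted p = 1.3e-07; adjusted p = 0.182 with an estimated correlation; permutation p = 0.01, or 0.185 adjusted over 37 lists). Of these 5 fell and none rose adjusted over the list alone, and 0 passed over all genes. Acadl, the long-chain acyl-CoA dehydrogenase, was 1.64-fold lower (-0.72 ± 0.11), the mitochondrial carnitine carrier Slc25a20 differed by -0.34 ± 0.06, Ppara by -0.29 ± 0.09 and Acadvl by -0.21 ± 0.06.

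Oxidative phosphorylation genes were also lower in POR-null mice, by -0.09 ± 0.05 with 34 of 36 members below 0 (camera adjusted p = 5.8e-11; adjusted p = 0.216 with an estimated correlation). Brush border genes were higher by 0.06 ± 0.14 (adjusted p = 0.0044; adjusted p = 0.33 with an estimated correlation), with the peptidase Mep1a at 0.42 ± 0.09 and the peptide carrier Slc15a1 at 0.26 ± 0.07 the 2 members that rose adjusted over the list alone, against 0 over all genes. T cell markers (0.07 ± 0.09), aryl hydrocarbon receptor targets (-0.08 ± 0.11) and bile acid and sterol handling genes (-0.18 ± 0.28) passed camera as well (adjusted p = 0.023, 0.038 and 0.02), not with an estimated correlation (adjusted p = 0.465, 0.33 and 0.242 with an estimated correlation), and had no member past the test adjusted over the list alone or over all genes. Each call depended on single pools. The T cell list was not called without wild-type control pool 2, wild-type quercetin pool 1, POR-null control pool 2 or POR-null quercetin pool 3 (mean 0.058, 0.051, 0.051 and 0.046). Nor was the bile acid list called without wild-type control pool 3, POR-null control pool 1 or POR-null quercetin pool 2 (-0.12, -0.12 and -0.15). The aryl hydrocarbon receptor list lost its call without wild-type control pool 2, wild-type quercetin pool 3, POR-null control pool 2 or 3, or POR-null quercetin pool 1 or 3 (-0.077 to -0.061). In data with no effect and the spread of these arrays, camera with its preset correlation called 6.8 lists on average, and 37 of 100 draws called as many as the 8 seen here. Among single genes with the smallest p, the serine protease Prss30 was higher in POR-null mice by 0.52 ± 0.07 (adjusted p = 0.0554), the lysosomal protease Lgmn by 0.77 ± 0.13 (0.0752), and Rpe (-0.35 ± 0.07), Tcim (-0.40 ± 0.08) and Lama3 (-0.38 ± 0.08) were lower. None of these passed.

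On the control diet alone, sterol genes were higher in POR-null mice by 0.65 ± 0.39 (1.57-fold; camera adjusted p = 5.4e-17). That call was lost with the correlation estimated (adjusted p = 0.249 with an estimated correlation), and the pools overlapped because of POR-null control pool 3. Adjusted over the list alone 14 of 19 members rose, among them Srebf2 (0.38 ± 0.10), Lss (0.49 ± 0.13), Fdft1 (1.37 ± 0.36) and Pmvk (0.65 ± 0.17), against 0 over all genes. Without pool 3, left out because of its sterol values, the list mean was 1.00 (2.01-fold), 9 members passed over all genes and the adjusted p was 0.0162 with an estimated correlation, which is no independent test of this list. Acadl was 2.01-fold lower (-1.01 ± 0.15), with no overlap between pools, and was the member of the fatty acid oxidation list that fell adjusted over the list alone; the list mean was -0.15 ± 0.28 (camera adjusted p = 0.00017; adjusted p = 0.249 with an estimated correlation). That mean was -0.097 without POR-null control pool 1 and -0.096 with the segment score as a covariate, still called in both cases.

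The control-diet comparison also held a set of differences that went with markers of intestinal segment. Distal markers were higher by 0.32 ± 0.45 and proximal markers lower by -0.18 ± 0.24 in POR-null pools (camera adjusted p = 0.00074 and 0.027; adjusted p = 0.255 and 0.334 with an estimated correlation). Of the distal markers 3 of 12 rose (Osr2 0.58 ± 0.11, Cubn 0.53 ± 0.15) and of the proximal 2 of 11 fell (Ada -0.58 ± 0.18) adjusted over the list alone, against 0 over all genes. Without wild-type control pool 1 neither list was called (distal mean 0.18). Nor was the proximal list called without wild-type control pool 2 or POR-null control pool 1 or 2 (-0.16 to -0.13 over these 4 pools). The distal mean was 0.51 without wild-type control pool 3. Beside them, T cell and intraepithelial lymphocyte markers were higher by 0.24 ± 0.20, with 6 of 14 members higher adjusted over the list alone (Ccl5 0.67 ± 0.15, Cd3g 0.50 ± 0.12, Gzma 0.45 ± 0.12), and glutathione S-transferases were lower by -0.21 ± 0.22, with 3 of 20 members lower (Gstm2 -0.50 ± 0.15, Gsta3 -0.27 ± 0.08, Gstm3 -0.62 ± 0.19). Their adjusted p were 2e-07 and 5.9e-06 by camera and 0.249 for each with an estimated correlation, and over all genes 0 members passed. With the segment score as a covariate, a setting chosen after seeing the data, the T cell mean was 0.17, still called, while the glutathione S-transferase mean was -0.068 and that list was no longer called. Interferon response genes were lower by -0.14 ± 0.25 (adjusted p = 0.0031; adjusted p = 0.507 with an estimated correlation), where 4 members fell, among them Oasl2 (-0.86 ± 0.16), Oas2 (-0.37 ± 0.10) and Bst2 (-0.41 ± 0.11), and Gbp2 (0.37 ± 0.11) rose adjusted over the list alone, against 0 over all genes. Without wild-type control pool 1 or POR-null control pool 3 this list was not called (mean -0.019 and -0.052), nor with the segment score as a covariate (-0.074), and without wild-type control pool 2 its mean was -0.22. Mep1a was 1.66-fold higher (0.73 ± 0.12) and the P450 Cyp1a1 1.58-fold lower (-0.66 ± 0.15), both with no overlap between pools, which chance gives for 10% of genes with 3 against 3. Each passed adjusted over its list alone and not over all genes.

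The other lists called on this diet were 7. Heat shock (-0.21 ± 0.16), oxidative phosphorylation (-0.12 ± 0.08), conjugation and hydrolysis (-0.11 ± 0.21), immediate early (-0.10 ± 0.14) and fat absorption genes (-0.09 ± 0.15) were lower, and brush border genes (0.11 ± 0.23) and nerve and glia markers (0.11 ± 0.03) higher, by camera. Ces1f (-0.70 ± 0.16) fell adjusted over the conjugation list alone, Clps, colipase, (-0.50 ± 0.10) over the fat absorption list alone, and Mep1a rose over the brush border list alone, against 0 over all genes. The lowest adjusted p of these 7 lists was 0.249 with an estimated correlation. Without wild-type control pool 1 the conjugation, fat absorption, brush border and nerve lists were not called, without wild-type control pool 3 the heat shock, immediate early and nerve lists. The same held without wild-type control pool 2 for conjugation and fat absorption, without POR-null control pool 1 for fat absorption, without pool 2 for conjugation, immediate early and nerve genes, and without pool 3 for immediate early and nerve genes. The means nearest to 0 in these cases were -0.098 for heat shock, -0.017 for fat absorption (without POR-null control pool 1), -0.059 for conjugation, -0.070 for immediate early, 0.084 for brush border and 0.076 for nerve genes. Of lists still called, heat shock had a mean of -0.33 without POR-null control pool 2, -0.32 without wild-type control pool 1 and -0.13 without POR-null control pool 3, conjugation of -0.21 without wild-type control pool 3, and fat absorption of -0.14 without POR-null control pool 3. Under the segment covariate the conjugation mean turned to 0.055 and the fat absorption mean was -0.014. Neither was called, nor were immediate early (-0.089) and nerve genes (0.10). The heat shock mean grew to -0.36, still called, and that of smooth muscle markers was -0.31, against -0.035 without the covariate. By limma 0 probe sets passed, with 1379 at an unadjusted p under 0.05. Without POR-null control pool 3, 24 passed, 23 of them higher, and without POR-null control pool 2, 1 passed. The 14 lists called were matched in 4 of 100 draws with no effect.

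On the quercetin diet the sterol genes separated the genotypes fully. All 19 members were higher in POR-null mice, by a mean of 0.79 ± 0.52 (1.72-fold), and every POR-null pool lay above every wild-type pool (exact permutation p = 0.1, the smallest that 3 against 3 pools allow). Adjusted over the list alone 16 members rose, including Hsd17b7 (0.64 ± 0.11), Hmgcs1 (1.49 ± 0.32, 2.81-fold), the isomerase Idi1 (1.27 ± 0.30) and Fdft1 (1.42 ± 0.36), against 0 over all genes. The list passed camera (adjusted p = 1.8e-29; adjusted p = 0.154 with an estimated correlation). Without POR-null control pool 3, whose spread enters the shared error and which was left out because of its sterol values, that adjusted p was 0.0173 with an estimated correlation. Fatty acid synthesis genes were higher by 0.19 ± 0.29 (camera adjusted p = 0.00037; adjusted p = 0.228 with an estimated correlation), where Acss2 (0.34 ± 0.10), Fasn (0.42 ± 0.14) and Scd2 (1.10 ± 0.36) rose adjusted over the list alone, and fatty acid oxidation genes were lower by -0.13 ± 0.16 (0.00029; adjusted p = 0.242 with an estimated correlation), where Slc25a20 (-0.42 ± 0.09) fell. Without wild-type quercetin pool 1 the fatty acid oxidation mean was -0.064 and the list was not called. The fatty acid synthesis mean was 0.29, still called, with the segment score as a covariate. Over all genes 0 members of either list passed.

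**Figure D2:**
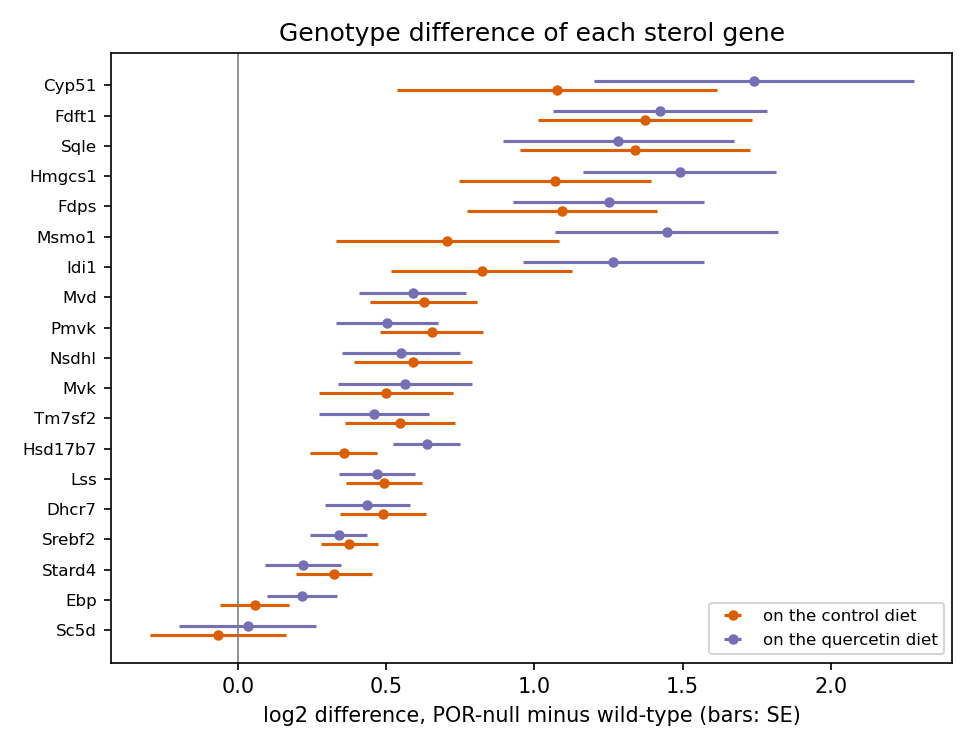
Log2 difference of POR-null minus wild-type pools for each of the 19 sterol genes on the control diet (orange) and on the quercetin diet (purple); points are limma estimates and bars their SE (3 pools per group). On the quercetin diet all 19 points lie above 0, and on the control diet 18 of them.

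Segment markers ran the other way on the quercetin diet. Distal markers were lower in POR-null pools by -0.45 ± 0.83 and proximal markers higher by 0.16 ± 0.26 (camera adjusted p = 0.00019 and 0.0074; adjusted p = 0.228 and 0.329 with an estimated correlation). Of the distal markers 6 of 12 fell (Cubn -0.61 ± 0.15, Guca2a -0.31 ± 0.10), and of the proximal Ada (0.72 ± 0.18) rose, adjusted over the list alone, against 0 over all genes. Bile acid handling genes were lower by -0.42 ± 0.75 (0.00029; adjusted p = 0.154 with an estimated correlation), but 4 of the 16 members are also distal markers, Slc51a, Fgf15 and Fabp6 among them. Over the 12 others the list did not follow the segment score within groups past the test (r = -0.14, exact permutation p = 0.596). The difference of these 12 alone on this diet was not computed, so that relation does not show that they fell. In this list the bile acid exporter subunit Slc51a (-0.41 ± 0.12) and the hormone Fgf15 (-0.62 ± 0.19) fell adjusted over the list alone. Fabp6, the ileal bile acid binding protein, differed by -2.94 ± 1.10, past the test over the distal list alone but neither over the bile acid list nor over all genes. Glutathione S-transferases (0.12 ± 0.16) and P450 genes (0.15 ± 0.32, with Cyp3a25 at 0.52 ± 0.17 and Cyp3a11 at 0.50 ± 0.19) were higher by camera (adjusted p = 0.008 and 0.0053; adjusted p = 0.461 for each with an estimated correlation), and no member of either passed. Without wild-type quercetin pool 3 (means 0.077, 0.033 and 0.067) or POR-null quercetin pool 1 (0.13, 0.11 and 0.15) the proximal, glutathione S-transferase and P450 lists were not called. The proximal mean was 0.27 and the glutathione S-transferase mean 0.20 without wild-type quercetin pool 1. Means under the segment covariate were -0.054 for glutathione S-transferases and 0.0057 for P450 genes, neither called. That of bile acid handling genes was -0.20, still called, with 4 members that also make up the score.

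The other lists called on this diet were MHC class II (-0.31 ± 0.32), T cell (-0.10 ± 0.14) and oxidative phosphorylation genes (-0.05 ± 0.05), all lower, and interferon response (0.09 ± 0.27), fibroblast (0.10 ± 0.12), circadian clock (0.14 ± 0.30) and B cell genes (0.22 ± 0.25), all higher. None of these 7 had an adjusted p under 0.228 with an estimated correlation, and each was lost without some single pool. MHC class II genes lost the call without wild-type quercetin pool 3 (mean -0.21) or POR-null quercetin pool 1 (-0.13), and T cell genes without wild-type quercetin pool 2 or 3 or POR-null quercetin pool 1 or 2 (-0.10 to -0.058). The same held for oxidative phosphorylation genes without wild-type quercetin pool 1 (-0.028), and fibroblast genes without POR-null quercetin pool 3 (0.076). Clock genes lost it without wild-type quercetin pool 3 or any POR-null quercetin pool (0.13 to 0.16), and B cell genes without wild-type quercetin pool 1 (0.12) or POR-null quercetin pool 3 (0.13). Interferon genes lost it without wild-type quercetin pool 1 (0.035) or POR-null quercetin pool 1 (0.089) or 2, where the sign turned (-0.044), and had a mean of 0.24 without pool 3. Under the segment covariate the means of MHC class II (-0.11), T cell (-0.017), interferon (0.0086) and clock genes (0.15) were not called. Those of B cell (0.37), fibroblast (0.15) and oxidative phosphorylation genes (-0.079) grew and were still called, and that of smooth muscle markers was 0.37, against 0.033 without the covariate. The largest clock difference was Dbp, at 0.87 ± 0.29, and Blnk (0.34 ± 0.10) rose adjusted over the B cell list alone. The steroid dehydrogenase Akr1c14 was 1.91-fold lower (-0.93 ± 0.19, adjusted p = 0.401) with no overlap between pools. By limma 0 probe sets passed, with 877 at an unadjusted p under 0.05; with only the 6 arrays compared in the fit 24 passed, 21 of them higher. Without POR-null control pool 3, 19 passed, and 1 passed without wild-type control pool 1, wild-type quercetin pool 1 or 2, or POR-null quercetin pool 3.

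The next question was what 24 hours of quercetin changed. In wild-type mice creatine kinase B, Ckb, fell 1.98-fold (log2 -0.98 ± 0.12, adjusted p = 0.0116), from 9.76 ± 0.31 to 8.78 ± 0.12 (SD, n = 3), and Osr2, a transcription factor, rose 1.69-fold (0.76 ± 0.11, adjusted p = 0.0322). A probe set of Gm9222, a gene model named after its values were seen because it makes up the count, rose by 0.95 ± 0.12 (adjusted p = 0.0116). These were the 3 probe sets past the test. At an unadjusted p under 0.05 there were 1972, against 1131 expected on average by chance. Probe sets are not independent and the spread of the expected count was not measured, so the excess alone is not evidence of an effect. Without wild-type quercetin pool 2 or pool 3 none passed, and without wild-type quercetin pool 1, 23 passed. Without wild-type control pools 1, 2 and 3 the counts were 11, 1 and 10.

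Genes of drug metabolism were lower in the quercetin pools of wild-type mice. Of 20 glutathione S-transferases 17 lay below 0 and 10 fell adjusted over the list alone, against 0 over all genes, with Gstk1 at -0.73 ± 0.18, Gstm3 at -0.78 ± 0.19, Gstm6 at -0.76 ± 0.19 and Gstm2 at -0.57 ± 0.15. The list mean was -0.32 ± 0.30, with no overlap between the pools (exact permutation p = 0.1, the smallest possible; camera adjusted p = 2.8e-11; adjusted p = 0.114 with an estimated correlation). Of 35 P450 genes and electron donors 3 fell adjusted over the list alone, among them Cyp1a1 (-0.73 ± 0.15) and Cyp2d22 (-0.38 ± 0.10), against 0 over all genes, and the mean was -0.19 ± 0.28 (camera adjusted p = 2e-04; adjusted p = 0.251 with an estimated correlation). Cyp3a11 differed by -0.52 ± 0.19 and did not pass. Of 24 conjugation and hydrolysis genes 3 fell adjusted over the list alone, against 0 over all genes: Ugdh, which makes UDP-glucuronate (-0.38 ± 0.09), the carboxylesterase Ces1f (-0.62 ± 0.16) and Papss2, which makes the sulphate donor (-0.71 ± 0.19). Their list mean was -0.18 ± 0.23 (camera adjusted p = 3.8e-05; adjusted p = 0.283 with an estimated correlation). Without wild-type quercetin pool 3 the P450 mean was -0.10 and the conjugation mean -0.11, and without wild-type control pool 2 the P450 mean was -0.12. The conjugation mean was -0.28 without wild-type control pool 3. Both lists were still called.

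Segment markers moved with these genes. Distal small intestine markers were higher in the quercetin pools by 0.55 ± 0.88, with 7 of 12 members higher adjusted over the list alone and Osr2 the member past the test over all genes (camera adjusted p = 1.5e-05; adjusted p = 0.154 with an estimated correlation). They included Cubn, the vitamin B12 receptor (0.63 ± 0.15), the gut hormone Pyy (0.64 ± 0.21) and Fabp6, at 7.62 ± 2.69 on control diet and 10.80 ± 1.66 on quercetin (3.17 ± 1.10). Proximal markers were lower by -0.32 ± 0.35 (3.8e-05; adjusted p = 0.151 with an estimated correlation), with 2 of 11 members lower adjusted over the list alone, against 0 over all genes, and adenosine deaminase Ada 2.06-fold lower (-1.04 ± 0.18). The segment score, distal minus proximal mean, was -0.75, -0.60 and 0.12 in the 3 wild-type control pools and -0.04, 0.57 and 0.87 in the 3 wild-type quercetin pools. With that score as a covariate, a setting chosen after seeing the data, the glutathione S-transferase mean was -0.08, the conjugation mean 0.11 and the P450 mean 0.025, none of them called, and none of the 3 probe sets passed. Of the 16 lists called in this comparison 3 were called with that covariate (oxidative phosphorylation genes at -0.11, and heat shock and fibroblast genes, whose means grew to -0.56 and -0.20). The 2 segment lists stayed among the lists tested with it, but their values are not given because they make up the score. Wild-type control pool 3, whose score lay apart from the other wild-type control pools, had the highest heat shock and fibroblast means of all pools (0.41 and 0.16). Whether that pool made these means grow under the covariate was not tested.

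**Figure D3:**
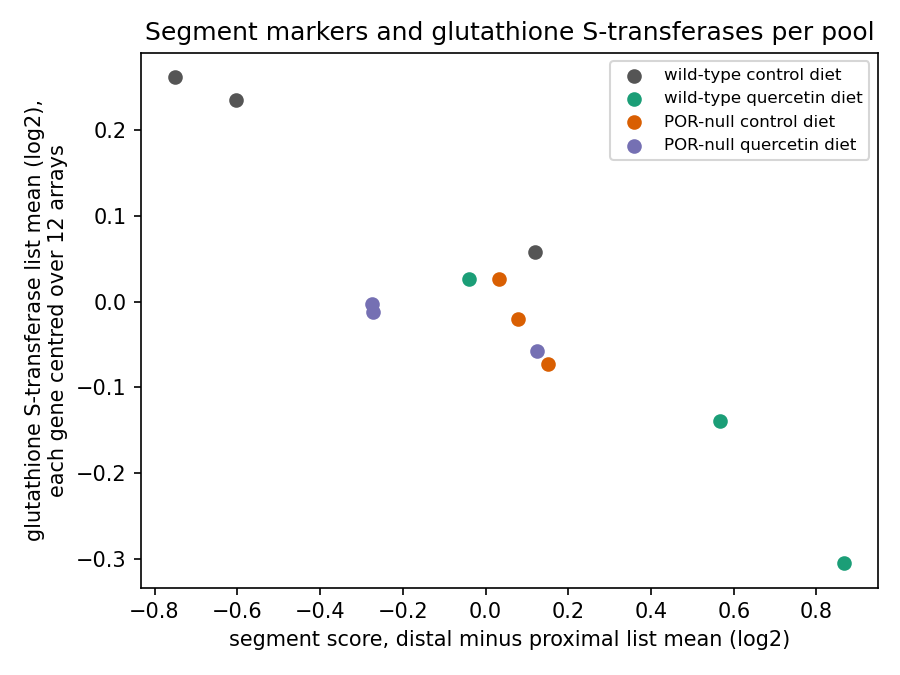
Mean log2 level of 20 glutathione S-transferase genes (vertical axis, each gene centred over 12 arrays) against the segment score (horizontal axis, distal minus proximal marker mean, log2) in each pool, coloured by group. The wild-type control pools reach down to a score of -0.75 and the wild-type quercetin pools up to 0.87, and the list mean is lower where the score is higher.

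Lymphocyte markers were higher and energy genes lower with quercetin in wild-type mice. All 14 T cell and intraepithelial lymphocyte genes lay above 0, with a mean of 0.28 ± 0.23 (0.15 and not called with the segment score as a covariate), and 5 rose adjusted over the list alone against 0 over all genes. The chemokine Ccl5 was 1.81-fold higher (0.85 ± 0.15), granzyme A (Gzma) higher by 0.56 ± 0.12, the integrin Itgae by 0.44 ± 0.12 and Cd3g by 0.40 ± 0.12. All 36 oxidative phosphorylation genes lay below 0, with a mean of -0.15 ± 0.09 and none past the test alone (Ndufb3 -0.34 ± 0.09, Ndufa5 -0.29 ± 0.08). Both lists passed camera (adjusted p = 3.6e-07 and 5.9e-14; adjusted p = 0.114 for each with an estimated correlation) and the directional test of fry (adjusted p = 0.0339 for each), as did the glutathione S-transferases (0.0458). Smooth muscle markers differed by -0.13 ± 0.15 in this comparison and were not called, but with the segment score as a covariate their mean was -0.63 ± 0.54.

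In the same comparison fatty acid oxidation genes were lower by -0.12 ± 0.25, where Ehhadh (-0.38 ± 0.09) and Acaa1b (-1.12 ± 0.27) fell adjusted over the list alone, and interferon response genes by -0.14 ± 0.26, where Oasl2 (-0.92 ± 0.16) and Bst2 (-0.48 ± 0.11) fell. The interferon mean was -0.018 without wild-type control pool 1 and -0.084 without wild-type quercetin pool 1, where the list was not called, and -0.22 without wild-type control pool 2. The fatty acid oxidation mean was -0.071 without wild-type quercetin pool 3 and -0.19 without pool 1, with the list still called. Heat shock (-0.30 ± 0.25), fat absorption (-0.19 ± 0.17), fibroblast (-0.12 ± 0.19), glucose and fructose (-0.10 ± 0.16) and NRF2 target genes (-0.08 ± 0.21) were lower, and cell cycle genes (0.15 ± 0.12) and nerve and glia markers (0.12 ± 0.06) higher, with no member of these past the test adjusted over the list alone. All 9 lists passed camera, of which NRF2, glucose and cell cycle genes lost the call without wild-type control pool 2 (means -0.056, -0.059 and 0.049) or wild-type quercetin pool 3 (-0.061, -0.053 and 0.10). Fibroblast markers lost it without wild-type control pool 1 (-0.11) or 3 (-0.069). Nerve markers lost it without wild-type control pool 1 or 3, wild-type quercetin pool 2 or 3, or POR-null control pool 3 (0.089 to 0.12). The means of lists still called were -0.19 for heat shock genes without wild-type control pool 3, -0.19 for fibroblast markers without wild-type control pool 2 and -0.16 for glucose genes without wild-type quercetin pool 1. Under the segment covariate the means were -0.026 for fatty acid oxidation, -0.019 for interferon, -0.055 for fat absorption, -0.012 for glucose, -0.044 for NRF2, -7.4e-05 for cell cycle and 0.11 for nerve genes. None of these 7 was called. Of the 9 lists none had an adjusted p under 0.154 with an estimated correlation. Nqo1, a target of both NRF2 and the aryl hydrocarbon receptor, differed by 0.00 ± 0.13, with its sign turned to -0.03 by quantile normalization and by median centring. The 16 lists called were matched in 2 of 100 draws with no effect.

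In POR-null mice quercetin changed no single probe set past the test by limma, with 910 at an unadjusted p under 0.05, against 1131 expected on average by chance. Oxidative phosphorylation genes were again lower, by -0.08 ± 0.06 with 34 of 36 below 0 and no overlap between pools (exact permutation p = 0.1, the smallest possible; camera adjusted p = 1.7e-05; adjusted p = 0.517 with an estimated correlation). The pancreatic enzyme list was higher by 0.12 ± 0.19 (0.019; adjusted p = 0.517 with an estimated correlation), with colipase Clps (0.48 ± 0.10) the member that rose adjusted over the list alone, against 0 over all genes. Sterol genes were higher by 0.26 ± 0.26 (0.002; adjusted p = 0.687 with an estimated correlation), with Hmgcs1 at 0.74 ± 0.32 and 0 members past the test. The sterol sign turned to -0.088 without POR-null control pool 3, with means of 0.46 and 0.41 without POR-null control pools 1 and 2. The pancreatic list was not called without POR-null control pool 3 or POR-null quercetin pool 2 (0.11 for each), nor with the segment score as a covariate (0.098).

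Cell cycle genes (0.11 ± 0.11) and goblet cell markers (0.12 ± 0.12) were also higher in POR-null mice on quercetin, and MHC class II (-0.28 ± 0.24), distal segment (-0.21 ± 0.37), fatty acid oxidation (-0.10 ± 0.17) and brush border genes (-0.09 ± 0.16) lower, all by camera. None had an adjusted p under 0.517 with an estimated correlation, and no member passed adjusted over its list alone. MHC class II genes were not called without POR-null control pool 1 (mean -0.18) or 2 (-0.22) or POR-null quercetin pool 1 (-0.10). Nor were distal markers without POR-null control pool 2 (-0.21) or POR-null quercetin pool 2 (-0.16). Cell cycle and fatty acid oxidation genes lost the call without POR-null control pool 3 (0.049 and -0.084) or POR-null quercetin pool 2 (0.043 and -0.061). Brush border genes lost the call without POR-null control pool 2 or 3 or POR-null quercetin pool 2 (-0.080 to -0.075), and goblet cell markers without these or POR-null quercetin pool 3 (0.092 to 0.11). Larger means came without POR-null control pool 3 for MHC class II (-0.44), POR-null quercetin pool 1 for cell cycle (0.20) and POR-null control pool 1 for fatty acid oxidation genes (-0.15). The fatty acid oxidation mean was -0.067 without POR-null control pool 2. Cubn differed by -0.50 ± 0.15 and Fabp6 by -1.27 ± 1.10. The glucose-6-phosphatase G6pc was 1.67-fold lower (-0.74 ± 0.16, from 8.73 to 7.99) with no overlap between pools. It passed adjusted over the glucose list alone, which was not called, and not over all genes (adjusted p of 0.995). Cyp1a1 (0.08 ± 0.15) and Cyp3a11 (0.05 ± 0.19) did not pass. The 9 lists called were matched in 31 of 100 draws with no effect.

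Whether the response to quercetin differed between genotypes was tested by the interaction, POR-null minus wild-type. By limma 0 probe sets passed, with 1141 at an unadjusted p under 0.05 and 2 past the test without wild-type control pool 1. Distal markers responded lower in POR-null mice by -0.77 ± 1.23, where 7 of 12 fell adjusted over the list alone (Osr2 -0.88 ± 0.15, Cubn -1.14 ± 0.21, Fabp6 -4.44 ± 1.56), and proximal markers higher by 0.34 ± 0.44, with Ada at 1.30 ± 0.26. Glutathione S-transferases responded higher by 0.32 ± 0.36, with 8 of 20 higher adjusted over the list alone (Gstm2 0.77 ± 0.21, Gstm3 0.97 ± 0.27), and T cell markers lower by -0.35 ± 0.30, with 5 of 14 lower (Ccl5 -0.92 ± 0.21, Itgae -0.75 ± 0.18). Over all genes 0 members of these lists passed. With the segment score as a covariate the interaction was 0.014 for glutathione S-transferases and -0.19 for T cell markers, and neither was called. Their adjusted p by camera were 3.6e-07, 0.00043, 3.6e-07 and 3.4e-07, in that order, and lay between 0.202 and 0.232 with an estimated correlation. Of the interferon genes 3 rose, among them Oasl2 (1.03 ± 0.23) and Bst2 (0.75 ± 0.16), and Gbp2 (-0.50 ± 0.15) fell adjusted over the list alone, against 0 over all genes, within a list that was higher by 0.24 ± 0.44 (0.00017; adjusted p = 0.516 with an estimated correlation). That list was not called without wild-type control pool 1 (0.11) or POR-null quercetin pool 2 (0.10), nor with the segment score as a covariate (0.082). Its mean was 0.15 and 0.38 without POR-null control pool 3 and POR-null quercetin pool 3. Across genes, the quercetin changes of the 2 genotypes correlated at r = 0.09 (exact permutation p = 0.6, 20 relabellings), where genes are not independent replicates.

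Averaged over both genotypes, Ckb was 1.57-fold lower on the quercetin diet (-0.65 ± 0.09, adjusted p = 0.026), and the probe set of Gm9222 was higher by 0.79 ± 0.08 (adjusted p = 0.00259). These 2 passed, with 1769 at an unadjusted p under 0.05, while in POR-null mice alone no probe set passed. The count was 8 without wild-type quercetin pool 1 and 5 without wild-type control pool 3. It was 1, higher, without any single POR-null pool or wild-type quercetin pool 2 or 3. With the dim filter none passed, and with quantile normalization or with the segment score as a covariate the count was 1. All 36 oxidative phosphorylation genes lay below 0, with a mean of -0.12 ± 0.05, and 2 of them fell adjusted over the list alone, Ndufb8 (-0.20 ± 0.05) and Ndufc1 (-0.25 ± 0.07), against 0 over all genes. The list passed camera (adjusted p = 6e-17; adjusted p = 0.168 with an estimated correlation) and fry (adjusted p = 0.0228), and an exact permutation within genotypes gave p = 0.005, the smallest possible, or 0.0617 adjusted over 37 lists. NRF2 targets, lower by -0.07 ± 0.15, and pancreatic enzymes, higher by 0.10 ± 0.09, reached the same permutation p and passed camera, though not with the correlation estimated (adjusted p = 0.168 for each with an estimated correlation). The relation of the pancreatic list to the segment score within groups did not pass after adjustment (r = -0.91, exact permutation p = 0.015, or 0.128 adjusted over 35 lists). The mean of the list was 0.13, still called, with that score as a covariate. Gpx2 (-0.41 ± 0.12) and Gclm (-0.33 ± 0.10), both glutathione enzymes, and Nqo1 (0.01 ± 0.09, with its sign turned to -0.01 by quantile normalization and by median centring) belonged to the NRF2 list, whose members did not pass adjusted over the list alone. The NRF2 list was not called without wild-type quercetin pool 3 (-0.058) or POR-null control pool 3 (-0.059), nor with the segment score as a covariate (-0.055).

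Fatty acid oxidation genes were lower with quercetin over both genotypes by -0.11 ± 0.16 (camera adjusted p = 2.2e-05; adjusted p = 0.178 with an estimated correlation), with Ehhadh (-0.30 ± 0.06) and Acaa1b (-0.70 ± 0.19) the 2 that fell adjusted over the list alone, against 0 over all genes. Glutathione S-transferases (-0.16 ± 0.15), conjugation genes (-0.12 ± 0.15, with Ugdh at -0.27 ± 0.06), P450 genes (-0.11 ± 0.16, with Cyp2d22 at -0.30 ± 0.07) and the proximal segment markers that moved with them (-0.15 ± 0.16) were lower. With the segment score as a covariate the means were -0.073 for glutathione S-transferases, still called, and -0.0065 for conjugation and -0.030 for P450 genes, no longer called. The P450 mean was -0.066 without wild-type quercetin pool 3. Paneth cell markers were higher by 0.20 ± 0.21 (0.015; adjusted p = 0.304 with an estimated correlation), where Pla2g2a (0.29 ± 0.08), Itln1 (0.49 ± 0.16) and Mmp7 (0.38 ± 0.14) rose adjusted over the list alone, against 0 over all genes. Cell cycle (0.13 ± 0.09), goblet (0.11 ± 0.10), T cell (0.10 ± 0.10) and sterol genes (0.20 ± 0.19) were higher and heat shock (-0.16 ± 0.19), fat absorption (-0.10 ± 0.11) and glucose and fructose genes (-0.08 ± 0.13, with G6pc at -0.42 ± 0.11) lower. The sterol mean was 0.022 without POR-null control pool 3 and 0.14 without wild-type control pool 1, called in neither case, and 0.30 without POR-null control pool 1. Goblet markers lost their call without POR-null control pool 3 (0.10) or wild-type control pool 1 (0.083), and Paneth cell markers without wild-type control pool 2, wild-type quercetin pool 3 or POR-null control pool 3 (0.15 to 0.16). Glucose genes lost it without wild-type quercetin pool 3 (-0.059) or POR-null control pool 2 (-0.058). Heat shock genes lost it without wild-type control pool 3 (-0.10), and their mean was -0.098, still called, without POR-null control pool 2. The cell cycle mean was 0.080 without wild-type control pool 2. The heat shock mean was -0.25, still called, under the segment covariate. There the means of Paneth (0.12), cell cycle (0.075), goblet (0.050), T cell (0.056), sterol (0.17), fat absorption (-0.052) and glucose genes (-0.049) were not called. None of the 16 lists had an adjusted p under 0.168 with an estimated correlation.

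Quercetin in wild-type mice and the POR-null genotype on the control diet were set against the same 3 wild-type control pools, and their changes correlated across genes at r = 0.60, with a covariance of 0.0123. Simulated groups with no effect against shared controls gave r = 0.47 (-0.22 to 0.90) and a covariance of 0.00748 (-0.0025 to 0.0233). Both observed values lay within these ranges. Genes are not independent replicates in these correlations. At an unadjusted p under 0.05, 291 genes changed in the same direction in both, against 34.5 for independent lists, and with 3 control pools that could not be split, the share of this overlap that those pools bring was not measured. Ccl5, Osr2, Oasl2, Cyp1a1 and the glutathione S-transferases named above were among the genes with the same sign in both comparisons. The genotype effects on the 2 diets, which share no pool, correlated at r = 0.02 (exact permutation p = 0.8, 20 relabellings).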

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

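The tests of explanations in this part were chosen after the results were seen, except the test of brightness. The results listed are gene lists whose response to quercetin differed between the genotypes by the interaction test of camera. None of the 16 passed with an estimated correlation (lowest adjusted p = 0.202), and 6 of 100 draws with no effect called as many.

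The mean response in POR-null mice was lower than in wild-type mice for distal segment markers (-0.77), MHC class II (-0.50), bile acid handling (-0.48), T cell (-0.35), nerve and glia (-0.17) and brush border genes (-0.091). It was higher for proximal segment markers (0.34), glutathione S-transferases (0.32), heat shock (0.28), interferon response (0.24), fibroblast (0.17), fat absorption (0.17), P450 (0.16), conjugation and hydrolysis (0.14), endoplasmic reticulum stress (0.13) and oxidative phosphorylation genes (0.073). With the segment score as a covariate, which was chosen after seeing the data, 10 lists were called, of which 5 were among the 16, conjugation and hydrolysis genes with the opposite sign (-0.24). The means were then -0.13 for MHC class II, -0.090 for bile acid handling, -0.19 for T cell, 0.014 for glutathione S-transferase, 0.082 for interferon response, 0.023 for oxidative phosphorylation and 0.0056 for fat absorption genes, none of them called, and 0.61 for heat shock genes, which were. P450 (-0.11) and nerve and glia genes (-0.16) were not called either. Means that grew and were still called were 0.32 for stress, -0.20 for brush border and 0.28 for fibroblast genes, and the mean of smooth muscle markers, not among the 16, went from 0.068 to 0.69. Of the 16 bile acid genes 4 are also distal markers and so part of the score. Single pools ended 10 of the 16 calls. Without wild-type control pool 1 the conjugation (0.097), brush border (-0.067), interferon (0.11) and nerve lists (-0.17) were not called, without pool 2 P450 (0.088), conjugation (0.079), bile acid (-0.40) and oxidative phosphorylation (0.044), and without pool 3 stress (0.074) and nerve (-0.14). Without wild-type quercetin pool 1 brush border (-0.034) was not, and without pool 3 P450 (0.072), conjugation (0.061), fat absorption (0.11) and oxidative phosphorylation (0.051). Without POR-null control pool 1 fat absorption (0.10) and stress (0.075) were not, without pool 2 P450 (0.087), conjugation (0.095), bile acid (-0.46), brush border (-0.078) and fibroblast (0.11), and without pool 3 bile acid (-0.39), brush border (-0.073) and stress (0.083). Without POR-null quercetin pool 1 P450 (0.16) and conjugation (0.11) were not, without pool 2 conjugation (0.11), bile acid (-0.43), brush border (-0.074) and interferon (0.10), and without pool 3 brush border (-0.091). Of lists still called, MHC class II had a mean of -0.32 without POR-null quercetin pool 1 and heat shock of 0.17 without wild-type control pool 3. The conjugation mean was 0.23 without that pool and 0.22 without wild-type quercetin pool 1, the stress mean 0.22 without POR-null control pool 2, and the interferon mean 0.15 and 0.38 without POR-null control pool 3 and POR-null quercetin pool 3. Cd74, the invariant chain of MHC class II, differed by -0.91 and the pseudokinase Trib3 of the stress list by 0.35, and neither passed. Cyp1a1 (0.80 ± 0.22) passed adjusted over the aryl hydrocarbon receptor list alone and not over all genes.

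Sterol genes lay at the wild-type level in POR-null control pool 3 (-0.47, against 0.63 and 0.53 in pools 1 and 2). An exchange with a wild-type control pool would need such a pool at the POR-null level, and the highest lay at -0.15. RNA degradation would raise the 3' minus 5' difference of the control transcripts, and that of actin was 0.79 in this pool against 0.68 to 0.99 in the other 11, and that of GAPDH -0.04 against -0.02 to 0.16. A genotype score from 50 genes outside the sterol and fatty acid lists, chosen without this pool, was -0.16, within the range of wild-type pools (-1.08 to 0.14) and below the other POR-null pools (lowest 0.08). With 20 such genes it was -0.43 (wild-type pools -1.50 to -0.31, lowest other POR-null pool 0.44), and with 100 it was -0.33 (-0.79 to 0.32, lowest 0.17). The ranges of the genotypes overlapped with 50 and 100 genes and were apart with 20, so lying in the wild-type range says little with 50 or 100 genes. Only members of the sterol and fatty acid lists were kept out of the score, so other genes that vary with them could remain. A low score therefore cannot tell a wrong label from a different sterol response. A wrong label or another genotype among the pooled mice is a candidate explanation, and a different sterol response of these mice stays open as untested.

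Glutathione S-transferase genes were lower with quercetin in wild-type mice (-0.32 ± 0.30). Of the 3 pools highest in smooth muscle only wild-type control pool 3 enters this comparison, and without the 3 the mean was -0.39. The list mean was 0.059 in that pool against 0.26 and 0.24 in the other wild-type control pools. Leaving it out could therefore only enlarge the fall, so the fit could not have argued for smooth muscle and decides nothing on it. That pool also had a higher segment score (0.12 against -0.75 and -0.60 in the other wild-type control pools). Within groups the mean of the 19 list genes that are not segment markers followed the segment score over the 12 pools (Pearson r = -0.93, Spearman rho = -0.94, exact permutation p = 0.00077 for each, the smallest possible, and 0.027 adjusted over 35 lists; r = -0.94 without the 2 pools farthest from the median score). With the score as a covariate the mean was -0.08 ± 0.14 and the list was no longer called (adjusted p = 0.132), because its mean shrank, so a difference in the position sampled along the intestine may account for much of the pattern. That fit also moved smooth muscle markers from -0.13 to -0.63, and why was not tested. An effect of quercetin on segment markers themselves would look alike and stays open.

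Oxidative phosphorylation genes were lower with quercetin over both genotypes (-0.12 ± 0.05, 36 of 36 members). Genes as bright outside the list had a mean of -0.040, and 0 of 10000 random lists of such genes reached the list mean. Those lists were drawn gene by gene, without the correlation between genes of a pathway. Their share therefore bears on brightness only and does not measure chance for a list whose genes vary together. With the segment score as a covariate the mean was -0.10 and the list was still called. Since the list was not called with an estimated correlation (adjusted p = 0.168), a response of these genes to quercetin remains a hypothesis, consistent with these tests only.

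Other splits of the arrays were counted for each number of called probe sets. For the average quercetin effect, 3 of 100 splits gave as many as the 2 called, with 7 the highest of the others. That share is under 0.05 for this comparison taken alone. It was not adjusted over the 7 comparisons, the 3 splits include the real one, and the count was 0 with the dim filter. Chance is therefore not excluded. For the interaction and the average genotype effect, where 0 were called, 100 of 100 splits gave as many (highest others 2 and 28), which a count of 0 fixes in advance, so these splits decide nothing. For quercetin in wild-type mice 1 of 10 splits gave as many as the 3 called (highest other 1), and for quercetin in POR-null mice and genotype on the control and quercetin diets 10 of 10 gave as many as the 0 called, again fixed in advance (highest others 1, 6 and 1). These 10 splits are too few for a share under 0.05.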

How the results depend on the processing

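The fits with the smooth muscle arrays left out or the segment score as a covariate, and the exact permutation of list means, were chosen after seeing the data. The cause of the changes given here was not tested, except where fewer arrays or genes were in the fit.

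Median centring kept the call of all 94 lists, the replicate block 92, the mean of all probe sets 89, quantile normalization 84, smooth muscle arrays left out 77, and the dim filter 68 of 91. With the segment covariate 40 of 84 were kept and 7 changed sign. Leaving out 1 array kept 991 of 1128 list calls. With an estimated correlation 0 of 94 lists were called, in each contrast 0.

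For quercetin in wild-type mice the count of 3 probe sets was 8 with the replicate block, 15 without the smooth muscle arrays, 0 with the segment covariate and 0 to 23 without 1 array. For genotype on the control diet the count of 0 became 0 to 24 without 1 array. For genotype on the quercetin diet it was 24 with only the arrays compared, 1 with the covariate and 0 to 19 without 1 array. For the interaction it was 1 with the covariate and 0 to 2 without 1 array. For the average quercetin effect the count of 2 was 1 with quantile normalization, 0 with the dim filter, 4 with trend and robust, 6 without the smooth muscle arrays, 1 with the covariate and 1 to 8 without 1 array. For the average genotype effect the count of 0 was 4 with trend and robust, 20 with array weights, 1 with 1 probe set per gene, 2 with the covariate and 0 to 47 without 1 array. Other counts stayed within 1.5 times.

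Fry called 3 lists for quercetin in wild-type mice, 1 for the average quercetin effect and 0 in each other contrast. The exact permutation called 0 for either average. The segment covariate gave 6 lists for quercetin in wild-type mice, 10 for the interaction and 6 for the average quercetin effect, and the dim filter 8 for genotype on the control diet. Without 1 array the number of lists was 4 to 13 for quercetin in POR-null mice, 7 to 16 for genotype on the control diet and 8 to 16 on the quercetin diet.

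With the segment covariate the mean turned for quercetin in wild-type mice in P450 (0.025), conjugation (0.11) and cell cycle genes (-7.4e-05), for genotype in conjugation genes on the control diet (0.055) and glutathione S-transferases on the quercetin diet (-0.054), and for the interaction in P450 (-0.11) and conjugation genes (-0.24). Without 1 array it turned for sterol genes with quercetin in POR-null mice (-0.088 without POR-null control pool 3, up to 0.46 without another) and interferon genes by genotype on the quercetin diet (-0.044 without POR-null quercetin pool 2, up to 0.24 without another).

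Replicate numbers were not taken as pairs. With the group mean of each probe set subtracted, same-numbered arrays of different groups correlated at -0.14 to 0.19, with 2 of 18 pairs over 0.1. By the same measure 4 of 12 arrays matched their own number best. Of 428 named values, 2 changed sign by each scaling, both of Nqo1. The alternative pseudocounts were not run, since the values are log2. Segment lists stayed among the lists tested with the score made from them, but their own values under it are not given. A left-out pool leaves 2 in its group, and dim probe sets near background limit what can be seen.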

Other observations

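The genes named in this part, except Cpa1, were chosen after their values were seen.

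Quercetin in wild-type mice moved brush border genes in both directions, so that the list mean was near 0 (-0.00 ± 0.37 over 22 genes) and the list was not called (camera adjusted p = 0.545). Adjusted over the list alone 4 members rose and 2 fell, against 0 over all genes. Mep1a (0.57 ± 0.12) and the glutamate carrier Slc1a1 (0.47 ± 0.14) rose, and trehalase Treh (-0.72 ± 0.18) and the folate carrier Slc46a1 (-1.03 ± 0.35) fell. With the segment score as a covariate, a setting chosen after seeing the data, the SD over the list was 0.17 instead of 0.37. Of 17 antimicrobial and acute phase genes 3 fell adjusted over the list alone, against 0 over all genes, with the lectins Reg1 at -2.02 ± 0.48 and Reg3a at -0.47 ± 0.12, and with that covariate the SD over the list was 0.26 instead of 0.69. The list was not called in any contrast (lowest adjusted p = 0.165). Of the circadian clock genes Bhlhe40, a repressor of the clock, fell (-0.56 ± 0.13) adjusted over the list alone, against 0 over all genes. The efflux transporter Abcc3 (-0.38 ± 0.10) fell and Abcb4 (0.28 ± 0.08) rose adjusted over a transporter list that was not called.

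Several lists were called in no contrast by camera. The lowest adjusted p over the 7 contrasts was 0.112 for adipocytes of the mesentery and for xenobiotic transporters, 0.172 for endothelium, 0.2 for enteroendocrine cells, 0.202 for smooth muscle, 0.204 for red blood cells and 0.425 for macrophages and dendritic cells. In wild-type mice on quercetin, the pancreatic enzyme Cpa1 (0.47 ± 0.08) and the globin Hba-a2 (0.31 ± 0.10) rose adjusted over lists that were not called there, against 0 over all genes. The Paneth cell genes Itln1 (0.66 ± 0.23) and Pla2g2a (0.35 ± 0.11) rose in POR-null mice on quercetin in the same way.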
